A study of Mus musculus with 36 samples.

How the data were processed

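RNA was measured by sequencing in 36 libraries of mouse bone marrow-derived macrophages (BMDM), which are bone marrow cells grown for 5 days with 20 ng/mL macrophage colony-stimulating factor, per the labels' protocols. The labels name a genotype, WT or NOS1 KO, and a treatment, control or 100 ng/mL lipopolysaccharide (LPS, a bacterial cell wall product) for 2 or 8 h. This makes 6 groups of 6 libraries. The labels give no animal, batch or sex, and no pairing of libraries beyond a genotype label that starts with BMDM in 1 library of each group. Replicate numbers were given in accession order and name a library only. Because nothing says that the libraries of a group came from separate cultures or animals, p-values measure the spread between these libraries, which may be technical.

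The deposited files hold raw read counts per gene, 1 file per library, with no normalization. Reads were counted with HTSeq on the mm10 build, per the submitters' processing notes. The aligner, the gene annotation, the HTSeq version and the strand setting are not given in the sources used here. Without a strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart, and reads of near-identical copies may be split between them. The files list 54232 Ensembl gene identifiers, of which 54165 were found in GENCODE release M21 (mm10), used here for symbols and positions. The remaining 67 kept their identifiers, and 104 symbols belonged to more than 1 identifier. The files held 0 rows for unassigned reads. Counts per library summed to between 8953489 and 18482551, which limits what could be seen of genes with few counts.

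Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr on the 6 groups, which left 12957 genes. Library sizes were scaled with the trimmed mean of M-values (TMM), and the CPM values given here are counts relative to these scaled library sizes. A quasi-likelihood model with 1 mean per group was fitted to all 36 libraries, so that all groups share an estimate of the spread. Each contrast was tested with the quasi-likelihood F test with Benjamini-Hochberg adjustment, and genes with an adjusted p below 0.05 were called. Standard errors (SE) of log2 fold changes were computed from the F statistic. The contrasts were LPS against control within a genotype label, 8 h against 2 h in WT-labelled libraries, KO-labelled against WT-labelled libraries at each time, and the interaction, which is the difference between the LPS responses of both genotype labels.

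The gene lists, the rule for named genes, the tests and a first group of alternatives were fixed before the data were examined. There were 29 gene lists, and 25 of them had at least 5 tested genes. These were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes and, as an alternative, with a correlation estimated from the data, both adjusted over the 25 lists. Lists were made for the pathways and cell types relevant to macrophages and LPS, including markers of other cell types that a marrow culture could hold. Genes named in the text follow a rule: the 6 largest called changes in each direction per contrast among genes with a mean log2 CPM of 2 or more (predicted genes with Gm numbers and Rik names left out), up to 2 called members of each list in each direction or else the member with the smallest p, the genes Nos1, Nos2, Nos3, Socs1, Socs3, Rela, Nfkb1, Nfkbia, Tnf, Il1b, Il6, Il12b, Il10, Arg1, Ifnb1 and Cxcl10, and every called gene where a contrast had 5 or fewer. Where a comparison of genotype labels had few calls, the remaining called genes were named after their values were seen. Some genes that the rule names are not reported here.

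Replicate pairs were compared with a chi-square per gene. Its value was above that of sampling noise in every pair, with a lowest value of 2.15, so no libraries were merged. The first principal component of log2 CPM, after each group's mean was subtracted, held 34.6% of the variance and separated 18 libraries from the other 18, with 3 of each kind in every group. These are called set A (replicates 1, 2 and 6) and set B (replicates 3, 4 and 5). The sets were found from the counts and are not in the labels, so values within each set are given beside most, but not all, pooled comparisons of the genotype labels.

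The first group of alternatives was DESeq2 size factors, no count filter, a filter of 1 CPM in 6 libraries, surrogate variables from sva 3.50.0, DESeq2 1.42.0 or limma-voom as the test, the compared groups alone, a term for a sex score, leaving out the 6 libraries whose genotype label starts with BMDM, a minimum log2 fold change of 1, an estimated correlation for lists, windows of 5 and 20 Mb in place of 10 Mb around Nos1, and leaving out each library in turn. Alternatives chosen after seeing the data were the library set as a term, each set alone, scaling by library totals alone, and leaving out 4 libraries in doubt, which are the 3 WT-labelled libraries with Xist reads and replicate 5 of the WT-labelled LPS 8 h group. A list of skeletal muscle markers was also added then. How a kept or lost difference in the size of the LPS response is judged was changed after its values were seen, from the sign of the median to the list test, with the preset correlation, and p-values of that family were adjusted over its 4 tests. Pseudogene transcripts were matched to other transcripts with blastn 2.17.0.

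The main test was tested on simulated data for the contrast of KO-labelled against WT-labelled controls, with 200 of 12957 genes changed. It recovered 80% of genes changed 2-fold and 98% of genes changed 4-fold, with 3 false calls. The list test found a simulated doubling of the chemokine list at 2 h (adjusted p = 5.15e-48) and called 0 other lists. The simulated genes varied independently of each other and held no library sets. False calls that come from correlated genes or from the sets could therefore not show in these simulations. Genes with counts near 0 in a group have fitted fold changes that depend on the prior count. List medians were therefore also computed with genes of 3 or fewer counts over a group set to the bound that a floor of 3 counts allows.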

Results

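The data set holds gene counts of 36 libraries of mouse bone marrow-derived macrophages, 6 for each combination of a genotype label (WT or NOS1 KO) and a treatment (control, LPS for 2 h, LPS for 8 h). Library totals ran from 8953489 to 18482551 counts. The title of the series concerns SOCS1, a feedback inhibitor of cytokine signalling, and a subset of the targets of NF-kB, the transcription factor that LPS activates. The libraries of each group fell into 2 unlabelled sets of 3, set A and set B. The median chi-square per gene was 15.99 for pairs within set A, 3.46 within set B and 52.74 for pairs across the sets.

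Nos1, the gene named in the KO label, encodes neuronal nitric oxide synthase (ENSMUSG00000029361, mm10 chromosome 5, 117781032 to 117958840). Its counts went against that label. Nos1 stood at 4.16 ± 1.04 CPM (SD, n = 6) in KO-labelled controls and at 0.065 ± 0.0988 CPM (SD, n = 6) in WT-labelled controls. At 2 h the means were 3.49 ± 0.653 and 0.0857 ± 0.111 CPM, and at 8 h they were 1.63 ± 0.404 and 0.158 ± 0.344 CPM (SD, n = 6 each). The raw counts were 10 to 83 in KO-labelled libraries, 720 in all, and 0 to 8 in WT-labelled libraries, 21 in all. A count per gene does not show which exons the reads came from, so a transcript that lacks a deleted part cannot be excluded. Groups are therefore named by their labels throughout, and every direction between KO-labelled and WT-labelled libraries rests on those labels.

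**Figure D1:**
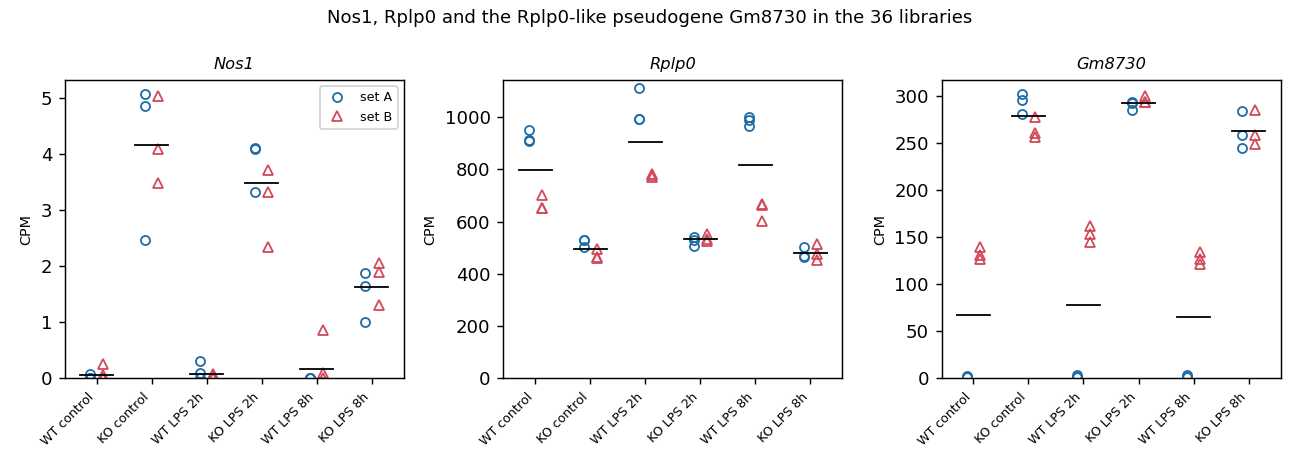
TMM-scaled CPM (y axis, linear) of Nos1, Rplp0 and the Rplp0-like pseudogene Gm8730 in each of the 36 libraries by group, with circles for set A, triangles for set B and a line at the group mean. Nos1 was higher in KO-labelled libraries, with means of 4.16 CPM against 0.065 CPM in controls, and Gm8730 stood near 1.73 CPM in WT-labelled controls of set A and 133 CPM in those of set B.

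In WT-labelled macrophages, 2 h of LPS raised inflammatory genes. Tnf, a proinflammatory cytokine (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007), went from 27.2 ± 5.34 to 2540 ± 89.6 CPM (SD, n = 6 each), a log2 fold change of 6.54 ± 0.23 (SE; edgeR adjusted p = 1.23e-22). All 30 measured NF-kB targets and feedback genes rose, with a median log2 fold change of 3.41. Among them were Nfkbiz (7.36 ± 0.19) and Nfkbia (5.26 ± 0.12), which both encode inhibitor of NF-kB family proteins. Of the inflammatory cytokines, 20 of 22 rose (median 5.85, or 5.39 with genes near 0 counts at their bound), and of the chemokines 17 of 18 rose (median 5.29). Cxcl10, an interferon-induced chemokine with 71 counts over the 6 control libraries, rose by 10.73 ± 0.43.

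Interferon-stimulated genes rose in 38 of 46 cases at 2 h (median 2.06; adjusted p = 0.193 for the list with an estimated correlation), and Gbp5, a guanylate-binding protein, rose by 8.66 ± 0.37. Classical activation effectors rose in 18 of 23 cases (median 2.14). Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), rose from 0.458 ± 0.779 to 23.4 ± 9.27 CPM (SD, n = 6 each). In the SOCS and JAK-STAT list 17 of 29 genes rose and 4 fell. Socs3 rose by 8.01 ± 0.31 and Socs1 (ENSMUSG00000038037, chromosome 16, 10782240 to 10785536) by 3.76 ± 0.30, from 1.33 ± 0.167 to 18.1 ± 7.43 CPM (SD, n = 6 each). Immediate early genes rose in 19 of 26 cases and fell in 2 (median 1.10; adjusted p = 0.168 for the list with an estimated correlation), with Dusp2 higher by 4.05 ± 0.27 and Jun lower at -1.79 ± 0.24. The largest falls named by the rule included Dusp6, a phosphatase of ERK kinases (-3.93 ± 0.20), and the homeobox gene Hhex (-3.61 ± 0.44).

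By edgeR, 4910 of 12957 genes were called between 2 h and control, 2627 higher and 2283 lower. Adjusted over the list alone, higher genes numbered 30 for NF-kB targets, 20 for cytokines, 17 for chemokines, 39 for interferon-stimulated genes, 19 for classical activation, 18 for SOCS and JAK-STAT and 19 for immediate early genes. Camera called 10 of 25 lists, and 6 of these held with an estimated correlation, among them NF-kB targets (adjusted p = 6.12e-10), cytokines (5.16e-07) and chemokines (9.9e-06). The interferon-stimulated and immediate early lists did not hold. Scaling by library totals alone lowered the median of all genes from -0.02 to -0.32 and the share of higher calls from 53.5% to 20.7%, so directions are relative to the TMM scale. The medians of the lists described here kept their sign.

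By 8 h the interferon-stimulated list had risen in all 46 measured members in WT-labelled libraries, with a median log2 fold change of 5.87 (adjusted p = 0.137 for the list with an estimated correlation). Gbp5 stood 11.43 ± 0.40 above control on the log2 scale. Nos2 reached 2680 ± 357 CPM (SD, n = 6), and all 23 classical activation effectors rose (median 4.58; adjusted p = 0.0581 with an estimated correlation). Genes of the cell cycle fell in 35 of 36 cases (median -3.11; adjusted p = 0.276 with an estimated correlation), with Cenpf, a kinetochore protein, at -5.91 ± 0.38 and Ccna2, cyclin A2, at -5.10 ± 0.49. MHC class I presentation genes rose in 20 of 21 cases (median 3.19; adjusted p = 0.0581 with an estimated correlation), among them the peptide transporter gene Tap1 (4.48 ± 0.25).

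The NF-kB list was higher in 29 of 30 cases at 8 h (median 3.77), the cytokines in 22 of 22 (median 6.15, or 5.83 with genes near 0 counts at their bound) and the chemokines in 17 of 18 (median 6.37). Tnf stood at 2790 ± 142 CPM and Nfkbia at 1330 ± 101 CPM (SD, n = 6 each). Socs1 reached 71.6 ± 9.97 CPM (SD, n = 6), a log2 fold change of 5.74 ± 0.31 over control, and Socs3 rose by 8.68 ± 0.32. In the SOCS and JAK-STAT list 20 of 29 genes rose and 7 fell, including Il6st, the shared receptor chain of the interleukin-6 family (-1.91 ± 0.17). Toll-like receptor signalling genes rose in 24 of 36 cases and fell in 7 (adjusted p = 0.0581 with an estimated correlation for both lists), with Tlr3 at 4.67 ± 0.23 and Sigirr, an inhibitory receptor, at -3.17 ± 0.29. Pparg, a lipid-responsive nuclear receptor in the alternative activation list, fell by 3.46 on the log2 scale (SE 0.17), while that list as a whole was not called (adjusted p = 0.2).

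By edgeR 9221 genes were called at 8 h, 4427 higher and 4794 lower. Adjusted over the list alone, all 46 interferon-stimulated genes, 23 classical activation effectors and 20 MHC class I genes were higher and 35 cell cycle genes lower. Camera called 12 of 25 lists, and 3 held with an estimated correlation: NF-kB targets (adjusted p = 3.93e-06), cytokines (0.00037) and chemokines (0.00241). Under library totals alone the median of all genes moved from -0.06 to -0.83 and the share of higher calls from 48% to 19.9%, and the medians of the called lists described here kept their sign. Skeletal muscle markers, a list added after seeing the data, summed to 4800 CPM in replicate 5 of this group and 132 CPM in its replicate 6, to 612 and 248 CPM in WT-labelled LPS 2 h replicates 6 and 5, and to at most 85 CPM in any other library.

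Between 2 and 8 h in WT-labelled libraries the interferon-stimulated list rose further in 44 of 46 cases (median 3.30) and fell in 1 (adjusted p = 0.408 for the list with an estimated correlation). Ifnb1, which encodes interferon beta, fell by 3.54 on the log2 scale (SE 0.35) over the same interval. Serpina3g, a serine protease inhibitor, rose by 9.80 ± 0.51, and Saa3, an acute phase protein, by 6.43 ± 0.64. Among cytokines Il23a fell by 3.73 (SE 0.40) and Lif by 3.06 (SE 0.29) on the log2 scale, while 15 of 22 rose and 5 fell (adjusted p = 0.408 for the list with an estimated correlation). Tnf (0.14 ± 0.18) and Nfkbia (-0.01 ± 0.10) were not called between these times, and the cell cycle list fell in 34 of 36 cases (median -2.58; adjusted p = 0.408 with an estimated correlation). EdgeR called 8131 genes, 3888 higher and 4243 lower. Camera called 7 of 25 lists, and 0 held with an estimated correlation. Under library totals alone the share of higher calls was 22.3% in place of 47.8%.

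In KO-labelled macrophages LPS also raised inflammatory genes. Tnf rose from 23.8 ± 7.48 to 2450 ± 237 CPM at 2 h (SD, n = 6 each; log2 fold change 6.68 ± 0.23). All 30 NF-kB targets rose at 2 h (median 3.18) and at 8 h (median 3.83), with 20 and 21 of 22 cytokines (medians 5.35 and 5.62) and 17 of 18 chemokines at both times (medians 4.51 and 5.06). With genes near 0 counts at their bound, the cytokine medians were 5.47 and 5.62. Interferon-stimulated genes rose in 29 of 46 cases at 2 h (median 1.33) and in all 46 at 8 h (median 4.84), with adjusted p = 0.379 and 0.176 for the list with an estimated correlation. Cell cycle genes fell in 34 of 36 cases at 8 h (median -2.80; adjusted p = 0.337 with an estimated correlation), and Nos2 rose from 0.655 ± 0.924 to 3920 ± 702 CPM (SD, n = 6 each). Socs1 rose by 3.70 ± 0.29 at 2 h and 5.76 ± 0.31 at 8 h.

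EdgeR called 4564 genes at 2 h in KO-labelled libraries (2444 higher, 2120 lower) and 9339 at 8 h (4526 higher, 4813 lower). Of the genes called at 2 h in both genotype labels, all 4051 moved in the same direction, where independent lists would share 1730, 869 of them in the same direction. At 8 h 8603 genes were called in both, 8602 in the same direction and 1 in the opposite one, where independent lists would share 6646, 3327 of them in the same direction. Across genes, which are not independent replicates, the fold changes of the labels correlated with r = 0.948 at 2 h and 0.968 at 8 h, over separate libraries. Camera called 10 lists at 2 h and 11 at 8 h, of which 6 and 3 held with an estimated correlation. Adjusted over the list alone, higher genes numbered 30, 20 and 17 at 2 h and 30, 21 and 17 at 8 h for NF-kB targets, cytokines and chemokines, and 32 and 46 for interferon-stimulated genes. Under library totals alone the share of higher calls fell from 53.5% to 20.3% at 2 h and from 48.5% to 19.5% at 8 h.

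**Figure D2:**
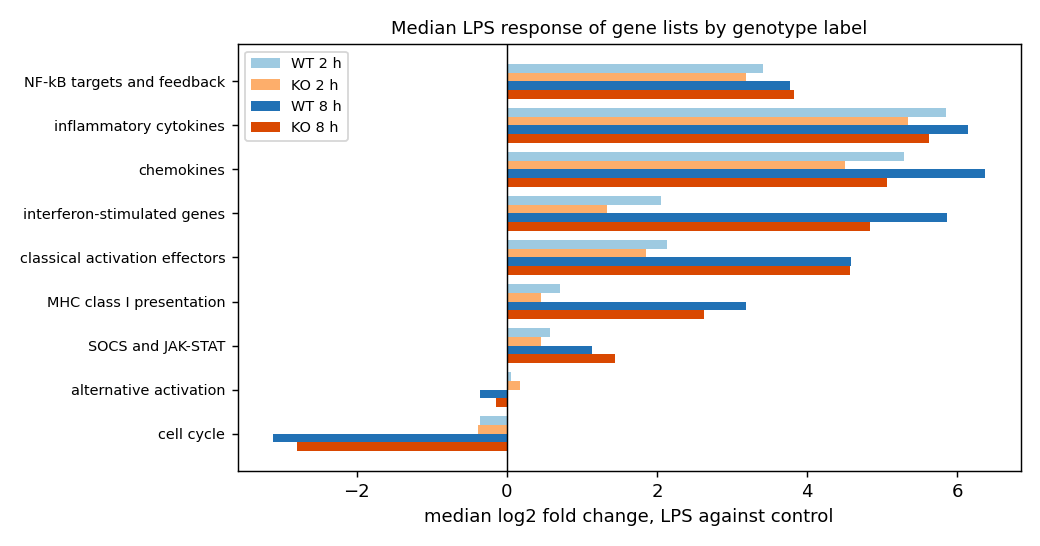
Median log2 fold change of LPS against control (x axis) for 9 gene lists, with a bar for each genotype label and time. NF-kB targets, cytokines and chemokines were high at both times, and interferon-stimulated genes went from 2.06 at 2 h to 5.87 at 8 h in WT-labelled libraries.

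The comparison of controls asked what differed between the genotype labels without LPS. Interferon-stimulated genes were higher in KO-labelled than in WT-labelled libraries in the pooled comparison. Irf7, a transcription factor that amplifies the type I interferon response (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481) stood at 131 ± 118 against 16.8 ± 14.1 CPM (SD, n = 6 each), a log2 fold change of 2.97 ± 0.58 (edgeR adjusted p = 0.0314). Ifit1 differed by 2.27 ± 0.46 (adjusted p = 0.0337) and Isg15, a ubiquitin-like interferon product, by 1.98 ± 0.39 (adjusted p = 0.0314). The difference lay in set B, where Irf7 was higher by 4.65, Ifit1 by 3.92 and Isg15 by 3.42; in set A the values were -0.03, -0.11 and -0.42, and none was called. Irf7 (adjusted p = 0.0791) and Isg15 (0.0541) were no longer called with the set as a term, and Ifit1 was (0.046). Each of the 3 genes exceeded the highest WT-labelled library in 3 of 6 KO-labelled libraries. That highest library was replicate 1, of set A, which held Xist reads.

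Of 46 interferon-stimulated genes 8 were called higher over all genes tested and 44 when adjusted over the list alone (median 1.23; camera adjusted p = 3.86e-117, and 0.00058 with an estimated correlation). The list median was -0.11 in set A (adjusted p = 0.331) and 2.18 in set B, and the difference between the sets had an adjusted p of 1.13e-176, or 3.35e-05 with an estimated correlation. MHC class I genes had a median of 0.31 with 0 of 21 called, or 5 adjusted over the list alone (adjusted p = 1.18e-18, and 0.0414 with an estimated correlation), and medians of -0.11 in set A and 0.78 in set B. Chemokines had 1 of 18 called, Cxcl10 (1.82 ± 0.39), or 5 adjusted over the list alone (median 0.40; adjusted p = 1.53e-08, and 0.0232 with an estimated correlation), and medians of -0.02 and 0.74 in the sets. Stromal cell markers were lower as a list with a median of -0.58 and 0 of 15 called, or 1 adjusted over the list alone (adjusted p = 8.93e-11, and 0.0336 with an estimated correlation), and medians of -0.16 and -1.04 in the sets. The list of nitric oxide synthesis, with Nos1 as the single called member of 17, was the remaining one of 5 lists, out of 15 called, that held with an estimated correlation (adjusted p = 0.00058). NF-kB targets had 0 of 30 called, with a median of 0.07, and -0.02 and 0.17 in the sets (adjusted p = 0.0359, and 0.494 with an estimated correlation). Neutrophil markers had medians of 0.66 in set A and -0.79 in set B. Erythroid and megakaryocyte markers summed to 121 ± 4.36 CPM in KO-labelled and 173 ± 2.65 CPM in WT-labelled controls of set B (SD, n = 3 each). T and NK cell markers summed to 268 ± 8.5 and 207 ± 5.29 CPM there, and B cell markers to 19.9 ± 2.1 and 20.1 ± 0.3 CPM. In set A the sums were 206 ± 18.5 and 176 ± 49.2, 150 ± 11 and 152 ± 4.62, and 14.1 ± 0.929 and 13.8 ± 1.22 CPM. Dendritic cell markers summed to 525 to 552 CPM in KO-labelled and 288 to 313 CPM in WT-labelled controls of set B, and to 337 to 405 and 360 to 402 CPM in those of set A. That list had 0 of 13 genes called and medians of 0.15 in set A (adjusted p = 0.928) and 0.14 in set B (adjusted p = 0.0416). Its member Bst2 stood at 219 ± 118 CPM in KO-labelled and 118 ± 23 CPM in WT-labelled controls (SD, n = 6 each). The sums can follow single genes and do not by themselves show more dendritic cells. Socs1 was not called (0.25 ± 0.34), with -0.33 in set A and 0.68 in set B.

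A second group of genes differed in both sets. Rplp0, which encodes an acidic ribosomal protein (ENSMUSG00000067274, chromosome 5, 115559467 to 115563727), stood at 496 ± 30.1 CPM in KO-labelled and 796 ± 141 CPM in WT-labelled controls (SD, n = 6 each). Its log2 fold change was -0.68 ± 0.12 (adjusted p = 0.00633), with -0.83 in set A and -0.49 in set B. Gcn1l1, a regulator of the translation kinase GCN2 (chromosome 5, 115565254 to 115622654), was higher by 0.73 ± 0.15 (adjusted p = 0.0392), by 1.21 in set A and 0.26 in set B. Gm14165, a pseudogene on chromosome 2, was higher by 1.27 ± 0.27 (adjusted p = 0.0436). It and the pseudogenes Gm8730 and Gm9625, named after their values were seen, match Rplp0 transcripts at 97.2%, 98.7% and 97.4% identity, so the counts of these 4 genes are uncertain. From WT-labelled to KO-labelled controls of set A, Rplp0 went from 924 to 519 CPM and Gm8730 from 1.73 to 293 CPM. In set B they went from 669 to 473 CPM and from 133 to 265 CPM. The lower Rplp0 count can therefore not be read as lower expression of Rplp0. The genes called in both sets were Nos1, Gcn1l1, Rplp0 and these pseudogenes in controls and at 2 h, 6 in all with the same direction in both sets, where independent lists would share 0.78 and 0.99, and 5 at 8 h (without Gcn1l1) where they would share 2.25. Rplp0 and the pseudogenes may share reads, so these counts do not stand for separate differences.

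In all, edgeR called 16 genes between the controls, 15 higher and 1 lower in KO-labelled libraries. Besides those named, they were Nos1, Oasl1, Ifit2, Rsad2, Cmpk2, Gvin1, Gbp3, Dtx3l and Gm20234. There were 7 calls in set A and 1407 in set B, and across genes the fold changes of the sets correlated with r = -0.069. The count was 67 without the libraries in doubt (3 WT-labelled libraries with Xist reads, and the WT-labelled LPS 8 h library with muscle transcripts), 3 without WT-labelled control replicate 2 and 73 without KO-labelled control replicate 2. It was 3 with no count filter and 1, Nos1, with the compared groups alone, where Irf7, Ifit1, Isg15 and Rplp0 were no longer called. With the set as a term 20 genes were called, 11 of them among the 16; Irf7, Ifit2, Isg15, Cxcl10 and Gvin1 were lost.

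**Figure D3:**
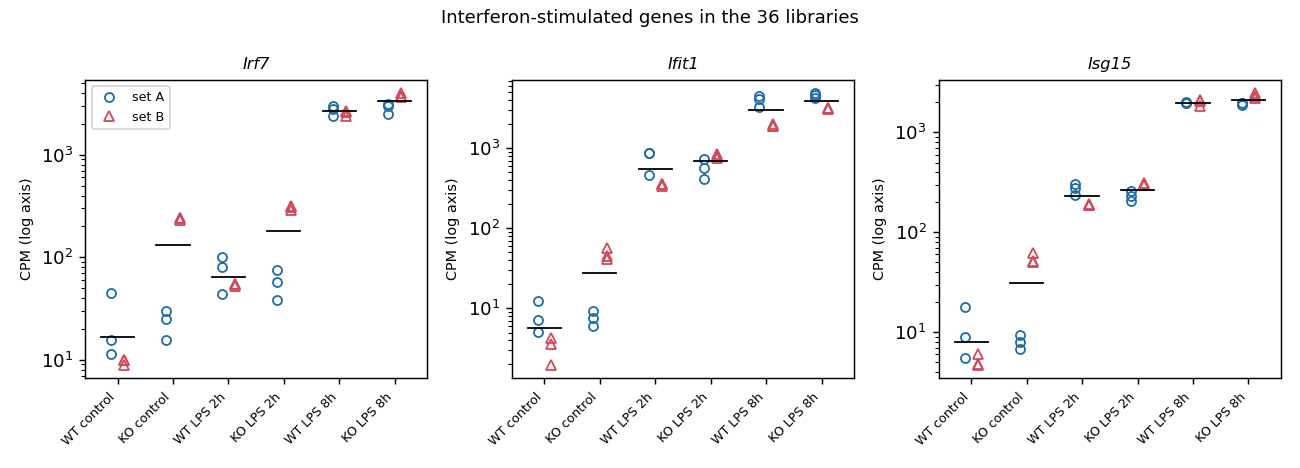
TMM-scaled CPM (y axis, log scale) of Irf7, Ifit1 and Isg15 in each of the 36 libraries by group, with circles for set A, triangles for set B and a line at the group mean. In KO-labelled controls the 3 libraries of set B averaged 239 CPM of Irf7 and those of set A 23.4 CPM, against 9.59 and 24 CPM in WT-labelled controls.

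After 2 h of LPS few genes separated the genotype labels. Rplp0 stood at 532 ± 16 CPM in KO-labelled and 904 ± 146 CPM in WT-labelled libraries (SD, n = 6 each; log2 fold change -0.77 ± 0.12, edgeR adjusted p = 0.00121), with -0.97 in set A and -0.52 in set B; its counts are uncertain as above. Nos1 was higher by 5.25 ± 0.56 (adjusted p = 8.68e-07), by 4.76 in set A; in set B, with 2 counts in WT-labelled libraries, the ratio of counts was 76.4 (95% counting interval 20.7 to 638). Ankrd55, an ankyrin repeat gene, was higher by 1.27 ± 0.25 (adjusted p = 0.0492), by 0.99 in set A and 1.54 in set B, and was not called with the compared groups alone. Interferon-stimulated genes had a list median of 0.46 with 0 of 46 called, or 2 adjusted over the list alone (camera adjusted p = 6.87e-17, and 0.516 with an estimated correlation), and medians of -0.39 in set A and 1.20 in set B. Stromal cell markers had a median of -0.52 with 0 of 15 called, or 2 adjusted over the list alone (adjusted p = 5.82e-10, and 0.087 with an estimated correlation), and -0.23 and -0.85 in the sets, and neutrophil markers had medians of 0.36 and -0.68 in the sets. Dendritic cell markers summed to 616 ± 6.24 CPM in KO-labelled and 356 ± 24 CPM in WT-labelled libraries of set B, and to 337 ± 8 and 370 ± 24.2 CPM in those of set A (SD, n = 3 each). Bst2, a member of that list, stood at 236 ± 144 CPM in KO-labelled and 130 ± 9.24 CPM in WT-labelled libraries (SD, n = 6 each). The sum can follow single genes and does not by itself show more dendritic cells. NF-kB targets had a median of -0.12 with 0 of 30 called (adjusted p = 0.000522, and 0.516 with an estimated correlation), -0.21 in set A and -0.06 in set B. Socs1 was not called (0.19 ± 0.24), with -0.70 in set A and 0.96 in set B. Rplp0, Nos1 and Ankrd55 were the 3 calls in the pooled comparison (2 higher, 1 lower), and camera called 8 of 25 lists, with 0 holding under an estimated correlation. A term for the set gave 9 calls, these 3 among them. Genes called numbered 9 in set A and 1398 in set B, and the fold changes of the sets correlated across genes with r = -0.012. With library totals alone 50% of the calls were higher in place of 66.7%.

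After 8 h of LPS Cxcl1, a neutrophil-attracting chemokine, stood at 13.1 ± 3.99 CPM in KO-labelled and 34.3 ± 19.1 CPM in WT-labelled libraries (SD, n = 6 each). Its log2 fold change was -1.40 ± 0.26 (edgeR adjusted p = 0.0128), with -0.32 in set A and -2.13 in set B. Rplp0 was lower at -0.76 ± 0.12 (-1.04 in set A, -0.43 in set B) and Nos1 higher by 3.26 ± 0.58. The Rplp0 counts are uncertain as above. Nos1 had 0 counts in the 3 WT-labelled libraries of set A, where it was at least 12.8-fold higher in KO-labelled ones (floor of 3 counts over the group), and 9 counts in those of set B (2.52), 8 of them in replicate 5, which held muscle transcripts. Without that library 1 count was left, and the ratio over both sets was 76.1 (95% counting interval 13.3 to 3038). Plcl2, a phospholipase C-like protein, was higher by 0.56 ± 0.11 (0.38 and 0.77 in the sets), and Me1, the cytosolic malic enzyme, was lower at -0.58 ± 0.12 (-0.40 and -0.78 in the sets). Srl, a protein of the muscle sarcoplasmic reticulum, was lower at -4.49 ± 0.96 (adjusted p = 0.0447; -1.23 and -5.36 in the sets). Srl stood at 58.4 CPM in WT-labelled replicate 5, which held 4800 CPM of skeletal muscle markers, and at 0.118 to 1.98 CPM in the other 11 libraries, and it was not called without the libraries in doubt (-1.01). Il1b (-1.16 ± 0.31, adjusted p = 0.0994), Nos2 (0.55 ± 0.38, adjusted p = 0.725) and Socs1 (0.28 ± 0.23, adjusted p = 0.795) were not called, with differences of -0.28, 0.18 and 0.19 in set A and -1.69, 0.89 and 0.36 in set B.

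The oxidative and nitrosative stress list was lower at 8 h with a median of -0.19 and 0 of 30 genes called, or 3 adjusted over the list alone (camera adjusted p = 3.8e-05, and 0.404 with an estimated correlation), with 0 in set A and -0.41 in set B. The cholesterol synthesis list moved apart between the sets, with medians of 0.35 in set A (adjusted p = 3.43e-07) and -1.02 in set B (adjusted p = 2.86e-37), and 0 of 24 genes called in the pooled comparison (median -0.13; adjusted p = 0.724 with an estimated correlation). Stromal cell markers had a median of -0.74 with 0 of 15 called, or 7 adjusted over the list alone (adjusted p = 2.09e-06, and 0.404 with an estimated correlation), and medians of -0.15 and -1.17 in the sets. Neutrophil markers had medians of 0.49 in set A and -0.57 in set B, and dendritic cell markers -0.18 and 0.34. The library with the muscle transcripts had the highest sum of stromal markers, 505 CPM, above every other library. Camera called 10 of 25 lists, and 0 held with an estimated correlation.

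EdgeR called 13 genes at 8 h, 7 higher and 6 lower. The others were Zfp949, 1500011B03Rik, Tmem110, Elmod2 and Ankle2, which were higher, and Abhd17c and Zfp369, which were lower. A term for the set gave 140 calls, these 13 among them. There were 7 calls in set A and 4075 in set B, and the fold changes of the sets correlated across genes with r = 0.095. With the compared groups alone edgeR called 0 genes, Cxcl1, Plcl2 and Me1 among those lost (1161 at an unadjusted p under 0.05), and with no count filter 6 were. The count was 2 without the libraries in doubt, 2 without WT-labelled LPS 8 h replicate 5 alone, and 121 without WT-labelled LPS 8 h replicate 2; under library totals alone 41 genes were called, 17.1% of them higher in place of 53.8%.

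Called genes lay near Nos1 more often than others. Of the genes called in any comparison of the genotype labels, Nos1 itself left out, 5 were among the 226 tested genes within 10 Mb of Nos1 and 22 among the other 12724 (odds ratio 13.1, 95% interval 3.83 to 35.8, two-sided Fisher exact test p = 9.14e-05). The 5 were Rplp0, Gcn1l1, Oasl1, 1500011B03Rik and Ankle2. The counts of Rplp0 are uncertain as above, and Oasl1 and Ankle2 were not called in set A alone. Oasl1 rose with LPS in WT-labelled libraries, from 4.15 CPM in controls to 1260 CPM at 8 h. Its call may therefore belong with the interferon-stimulated genes and not with nearness to Nos1, which was not tested. Within the sets the odds ratio was 57.4 in set A and 0.982 in set B. In set B 82 of 225 near genes and 4698 of 12743 others were called, and so many calls can hide a few near Nos1.

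The interaction asked whether the LPS response itself differed between the genotype labels. At 8 h the response of chemokines was smaller in KO-labelled libraries by a median of -0.63 (camera adjusted p = 1.89e-11, and 0.0128 with an estimated correlation), by -0.14 in set A (adjusted p = 0.307) and -0.88 in set B (adjusted p = 8.62e-15). The interferon-stimulated list differed by -0.86 at 2 h and -1.05 at 8 h (adjusted p = 0.103 and 0.101 with an estimated correlation). Within set A its values were -0.30 and 0.21, and within set B they were -1.14 and -1.83. A higher control level in KO-labelled libraries makes such a difference negative even where the level after LPS is not lower. Irf7 stood at 131 CPM in KO-labelled and 16.8 CPM in WT-labelled controls, and at 3320 and 2640 CPM at 8 h. Of the chemokines, Cxcl10 stood at 2.89 and 0.856 CPM, then at 5050 and 4250 CPM, while Cxcl1 was lower at 8 h (13.1 and 34.3 CPM). The response of Socs1 differed by -0.06 ± 0.41 at 2 h (-0.36 in set A, 0.28 in set B) and 0.03 ± 0.44 at 8 h (0.53 and -0.32). That of Tnf differed by 0.14 ± 0.25 at 2 h (0.63 and -0.29) and -0.16 ± 0.25 at 8 h (0.63, and -1.07 in set B with adjusted p = 0.00212). Chemokines that differed numbered 0 of 18, or 5 adjusted over the list alone at 8 h, and interferon-stimulated genes 0 of 46, or 11 and 15 adjusted over the list alone. EdgeR called 0 genes at either time, with 153 and 540 at an unadjusted p under 0.05. DESeq2 called 0 and 4, and limma-voom called 1 and 311, while set B alone gave 147 and 2162 and set A alone 0 and 0.

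Over the 1777 genes that responded to LPS by at least 1 on the log2 scale at 2 h, the response of KO-labelled libraries differed from that of WT-labelled ones by a median of -0.113 in the direction of the response. Genes raised by LPS rose less as a group (camera adjusted p = 2.26e-09 over the 4 tests of response size, and 0.0348 with an estimated correlation), and genes lowered by LPS fell less (8.24e-05, and 0.0128 with an estimated correlation). The median was -0.114 in set A and -0.111 in set B. With an estimated correlation the adjusted p was 0.728 in set A and 0.0151 in set B for raised genes and 0.332 and 0.00225 for lowered ones, and with DESeq2 size factors, another scaling, 0.067 and 0.00812 over both sets. It was 0.0918 for raised and 0.0196 for lowered genes with the set as a term. At 8 h the median was 0 over 5099 genes (camera adjusted p = 0.881).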

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

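Tests chosen only after the result was seen were that of an effect in both library sets, those of flanking DNA, processed copies and 1 copy near Nos1, and those of tissue and of Gm8730 for the muscle transcripts. The reading of the tissue test was also changed after its result was known, and splits within the sets were added after the first splits were seen. Groups of 6 libraries were tested for a library far from the others in 156 cases, of which 21 stood out, and chance gives about 1 in 20. The difference in LPS response between the genotype labels was tested for each list at each time, and 13 were called with the preset correlation. As many lists were called in 33 of 40 splits of the libraries between the labels at 2 h and in 28 of 40 at 8 h, the real split included.

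Interferon-stimulated genes were higher in KO-labelled controls, and the list's LPS response differed by -0.86 at 2 h and -1.05 at 8 h. An effect of the genotype label of similar size in both sets is argued against by set A, where the list median in controls was -0.11 (set B 2.18). WT-labelled control replicate 1 of set A, which held Xist reads, had more Irf7 (45.1 CPM) than replicates 2 and 6 (15.6 and 11.3 CPM). KO-labelled controls of set A held 15.5 to 29.7 CPM. The set A median without that library was not computed, so a smaller effect in set A is left open. Reads from LPS-treated libraries would bring all LPS-induced genes, but in set B the excess in KO-labelled controls was 4.19% of the LPS 8 h level for the list and 0.39% for other LPS-induced genes. A stimulus like 2 h of LPS is argued against in set B. NF-kB targets and cytokines moved there by 5.31% of their log2 response at 2 h and the list by 72.85%. An earlier or longer LPS-like stimulus was not tested and is left open. An interferon response in the cultures or animals behind the KO-labelled libraries of set B may account for the higher list. So may an effect of genotype in that set alone, and neither was tested.

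Genes called between the genotype labels lay near Nos1, and Nos1 itself was higher in KO-labelled libraries. With the set as a term, 9 of 226 genes within 10 Mb were called against 147 of 12724 others (odds ratio 3.55, Fisher exact p = 0.00166), as DNA carried along with a targeted allele could give, while set B alone gave an odds ratio of 0.982 (95% interval 0.737 to 1.3). There 82 of 225 near genes and 4698 of 12743 others were called, so a few calls near Nos1 could not stand out. Rplp0 and Oasl1, whose calls have the limits given above, were among the 9. Reads may move between Rplp0 and its copies, since 100% of the called pseudogenes with a match, 3 of 3, matched Rplp0, which was lower. In controls of set A, Rplp0 stood at 519 CPM in KO-labelled and 924 CPM in WT-labelled libraries, and Gm8730 at 293 and 1.73 CPM. The lower Rplp0 count went with higher counts of its copies, so it does not by itself show lower expression of Rplp0. In WT-labelled libraries of set B the level of Gm8730 and Gm9625 was 49.2% of that in KO-labelled ones at the median (45.1 to 52.4%), and about 1% in set A (0.62 to 1.53%), which is consistent with 1 copy of a variant Rplp0 in those libraries. Nos1 had 0 to 3 counts in the WT-labelled controls of set B, so that copy would have to come without the raised Nos1, and the crosses behind the libraries are not given in the sources used here.

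Skeletal muscle markers summed to 4800 CPM in WT-labelled LPS 8 h replicate 5, 612 and 248 CPM in WT-labelled LPS 2 h replicates 6 and 5, 132 CPM in LPS 8 h replicate 6 and at most 85 CPM elsewhere, and its Nos1 level of 0.855 CPM stood apart from its group. A mixture with a KO-labelled library is argued against by Gm8730, which lay -7.3% of the way to the KO-labelled level where Nos1 would need 47.5%. Rplp0 lay 34.2% and Gcn1l1 96.9% of the way, but Gcn1l1 levels of both labels overlapped in set B and 8 counts of Nos1 fix no share, so these decide nothing. Tissue from the dissection may be the source: 2 of 3 marker sums exceeded every other library (stromal 505 CPM), while erythroid markers did not (220 against 273 CPM). Their level in every library could hide a small share, so tissue stays open, also as a source of the Nos1 reads. At 2 h Nos1 was also highest in WT-labelled replicate 6, with 4 counts and 612 CPM of muscle markers, while replicate 5, with 248 CPM, had 1 count. In WT-labelled controls Nos1 was highest in replicate 3, with 3 counts and 18.6 CPM of muscle markers. Whether Nos1 reads came with the muscle transcripts was not tested.

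Replicate 1 of each WT-labelled group held Xist counts of 4924 in controls, 6526 at 2 h and 6093 at 8 h, where every other library had at most 1. These 3 libraries held 0 counts of Ddx3y, a Y chromosome gene, and the others held 484 to 1338. By these counts the 3 were female and the others male, so sex was not balanced between the genotype labels. In WT-labelled controls, replicate 3 had the fewest genes detected (16685) and the highest Nos1 (0.255 CPM), Nos2 (2.04 CPM), Il1b (1.87 CPM) and Cxcl10 (2.12 CPM). Muscle markers reached 77.9 CPM in replicate 1 of that group. At 2 h, Nos1 was highest in WT-labelled replicate 6 (0.3 CPM) and erythroid markers lowest in replicate 1 (56.6 CPM). At 8 h, erythroid markers were lowest in WT-labelled replicate 1 (137 CPM), and replicate 6 had the highest Socs1 (90.9 CPM) and the lowest Il10 (27.2 CPM). In KO-labelled controls, replicate 5 had the most genes detected (18617), replicate 3 the highest Nos2 (2.48 CPM) and Il12b (0.67 CPM), and replicate 6 the highest Nfkb1 (77.1 CPM). Nfkb1 was lowest in KO-labelled LPS 2 h replicate 2 (302 CPM).

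The LPS response at 2 h was smaller in KO-labelled libraries by medians of -0.18 for NF-kB targets, -0.27 for chemokines, -0.23 for classical activation, -0.08 for SOCS and JAK-STAT, -0.07 for toll-like receptor signalling and -0.20 for MHC class I. At 8 h the medians were -0.55 for cytokines, -0.63 for chemokines, 0.37 for the cell cycle, -0.09 for oxidative and nitrosative stress and -0.18 for MHC class I. With an estimated correlation the chemokines at 8 h held (adjusted p = 0.0128) and the other 12 did not. Set A alone called 9 lists of the interaction at 2 h and 0 at 8 h, and set B alone called 5 and 7. For lists raised by LPS, a higher control level in KO-labelled libraries can also make these medians negative.

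Other splits of the same libraries were drawn, 40 for comparisons of the genotype labels and 30 for LPS, the real split included. Each library was taken as a separate unit, so the splits ask whether chance between libraries, not between cultures or animals, can be excluded. For LPS it can be excluded in all 5 comparisons, with 1 of 30 splits each: 4910 genes against at most 38 in the others for WT-labelled libraries at 2 h, 9221 against 12 at 8 h, 8131 against 4572 between the times, 4564 against 0 for KO-labelled libraries at 2 h and 9339 against 0 at 8 h. For genes called between the genotype labels it cannot when splits ignore the sets: 5 of 40 splits gave as many in controls (16, highest other 512), 3 of 40 at 2 h (3, highest other 2586) and 6 of 40 at 8 h (13, highest other 905). Those highest counts point to a structure of the samples, which the 2 sets show. For the interaction, where 0 genes were called, any split gives as many, so the splits say nothing of chance (40 of 40 at 2 h, highest other 12, and at 8 h, highest other 120). For lists called, no other split gave as many in controls (15, highest other 12, 1 of 40). There 0 lists were called in both sets in the same direction and 2 in opposite ones. Libraries of a set may be technical, so chance between cultures is not excluded for these lists. Chance is not excluded at 2 h (8, highest other 18, 28 of 40) or at 8 h (10, highest other 10, 5 of 40). Nor is it for the interaction at 2 h (7, highest other 17, 33 of 40) and 8 h (6, highest other 14, 28 of 40). The other splits called a median of 8 lists in controls, 9 at 2 h and 5 at 8 h, so a list called with the preset correlation is not by itself evidence of a difference between the labels.

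A further 40 splits kept 3 libraries of each set in every group, again with each library as a separate unit. Chance can then be excluded for genes called at 2 h (3, highest other 0; 1 of 40), and not in controls (16, highest other 31; 2 of 40) or at 8 h (13, highest other 39; 2 of 40). With the set as a term it can be excluded at 2 h (9, highest other 0; 1 of 40) and not in controls (20, highest other 23; 2 of 40) or at 8 h (140, highest other 223; 2 of 40). For genes of the interaction these splits again say nothing of chance (40 of 40 at both times, 0 called and highest other 0). For lists, no other split gave as many in controls (15, highest other 12, 1 of 40) or at 8 h (10, highest other 7, 1 of 40). Chance is not excluded for the lists in controls, as above, or for those at 8 h, which did not hold with an estimated correlation. Nor is it at 2 h (8, highest other 16, 21 of 40) or for the interaction at 2 h (7, highest other 15, 19 of 40) and 8 h (6, highest other 14, 17 of 40). The other splits within the sets called a median of 6, 8 and 2 lists in controls, at 2 h and at 8 h.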

How the results depend on the processing

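Alternatives chosen after seeing the data were the set as a term, each set alone, library totals alone and leaving out the libraries in doubt. The cause of a change was not tested unless fewer genes or libraries entered the test by construction. No paired analysis was made because the labels give no replicate numbers or animals. A genotype label that starts with BMDM ties 1 library of each group, replicate 6, and ties no others. Some values recur at a replicate number, such as Xist reads in replicate 1 of every WT-labelled group. They were not used to pair libraries, so the LPS and interaction tests ignore any pairing. The set as a term is the closest fit with a block, found from the counts.

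For LPS, a minimum log2 fold change of 1 left 1783 (WT-labelled 2 h), 5011 (8 h), 3858 (8 h against 2 h), 1633 (KO-labelled 2 h) and 5128 (8 h) genes, and library totals alone gave 7608 and 7266 at 2 h in WT-labelled and KO-labelled libraries. All other alternatives run for these 5 counts stayed within 1.5 times. Leaving out 1 library gave 4594 to 4777, 9090 to 9195, 7944 to 8198, 4243 to 4419 and 9181 to 9255 genes in the same order.

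Between the genotype labels in controls, the 16 genes became 3 with no count filter, 54 with surrogate variables, 79 with the sex score, 7 in set A, 1407 in set B, 67 without the libraries in doubt, 1 with the groups compared alone, 87 by DESeq2 and 302 by limma-voom. At 2 h the 3 genes became 35 with surrogate variables, 9 with the set as a term, 9 in set A, 1398 in set B and 548 by limma-voom. At 8 h the 13 genes became 6 with no count filter, 104 with surrogate variables, 20 without the libraries whose label starts with BMDM, 27 with the sex score, 140 with the set as a term, 7 in set A, 4075 in set B, 41 with library totals alone, 2 without the libraries in doubt, 0 with the groups compared alone, 101 by DESeq2, 1619 by limma-voom and 3 with the minimum fold change. For the interaction the 0 genes became 147 in set B and 1 by limma-voom at 2 h, and 8 with surrogate variables, 1 with the set as a term, 2162 in set B, 4 by DESeq2 and 311 by limma-voom at 8 h. The 6 surrogate variables correlated with the set at up to 0.97.

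Leaving out 1 library gave 3 to 73 genes in controls, and 11 of 12 libraries moved the count by over 1.5 times. It was 73, 57 and 50 without KO-labelled replicate 2, WT-labelled replicate 1 and KO-labelled replicate 6, and 3 or 4 without WT-labelled replicates 2 to 6 or KO-labelled replicates 3, 4 or 5. The range was 2 to 3 at 2 h and 2 to 121 at 8 h. At 8 h it was 121, 70 and 53 without WT-labelled replicates 2, 6 and 1, 40 and 38 without KO-labelled replicates 2 and 1, 2 without WT-labelled replicate 5, and 3 without KO-labelled replicates 3 or 4. For the interaction it was 0 to 0 at 2 h and 0 to 1 at 8 h (1 without KO-labelled LPS 8 h replicate 2).

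With an estimated correlation, lists called fell to 6 and 3 for LPS in WT-labelled libraries at 2 and 8 h, 0 between the times, 6 and 3 in KO-labelled libraries, 5, 0 and 0 between the genotype labels in controls, at 2 h and at 8 h, and 0 and 1 for the interaction. In set B, 13 lists were called between the times and 15 between the labels at 2 h, and 13 at 2 h without the libraries in doubt. In set A, 4 were called between the labels in controls, 2 at 8 h and 0 for the interaction at 8 h. Surrogate variables gave 4 between the labels at 8 h, and 11 and 10 for the interaction.

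The odds ratio of calls near Nos1 was 0.982 in set B alone and stayed past the threshold under the 6 other alternatives run. Of 58 fold changes recomputed, 3 turned in set A alone, to -0.03 for Irf7, -0.11 for Ifit1 and -0.42 for Isg15, and 21 others lost their call there. With the groups compared alone 26 lost their call, with no count filter 21 did, without the libraries in doubt 12, without the libraries whose label starts with BMDM 9, with the set as a term 5, with surrogate variables 4, and 1 each with the sex score, DESeq2 size factors, DESeq2 and limma-voom. The median difference in LPS response size stayed on its side of the threshold in every alternative run, by the test with a preset correlation; with an estimated one, that of LPS-raised genes at 2 h held without the libraries whose label starts with BMDM (adjusted p = 0.0406) and in set B (0.0151), and under the other alternatives the adjusted p was 0.064 to 0.728. That of LPS-lowered genes at 2 h was lost with no count filter (0.106), with no minimum size of the response (0.064) and in set A (0.332), and held under the others (0.00106 to 0.0196). Genes with few counts, Nos1 among them, have fold changes that the depth leaves imprecise.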

Other observations

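Lipid genes moved in different directions in WT-labelled macrophages at 8 h of LPS. Ch25h, which makes 25-hydroxycholesterol, rose by 5.66 ± 0.88 (log2 fold change ± SE, n = 6 per group; edgeR), and the liver X receptor gene Nr1h3 rose by 2.68 ± 0.14. Scd2, a fatty acid desaturase, changed by -3.10 ± 0.48 and Dhcr7, a late enzyme of cholesterol synthesis, by -2.02 ± 0.16. Of 24 cholesterol synthesis genes 5 rose and 5 fell, or 4 and 4 adjusted over the list alone, and the list was not called (adjusted p = 0.86). Liver X receptor targets rose in 6 of 15 cases and fell in 4, also when adjusted over the list alone, and were not called (adjusted p = 0.397).

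Energy metabolism genes also moved in different directions at 8 h. Pfkfb3, which drives glycolysis, rose by 3.06 ± 0.41, while the glucose transporter gene Slc2a3 changed by -2.15 ± 0.29. Of 31 glycolysis and hypoxia genes 10 rose and 10 fell, the same numbers as when adjusted over the list alone (adjusted p = 0.874 for the list). Of 42 genes of mitochondrial respiration and the TCA cycle 19 rose and 6 fell, or 18 and 6 adjusted over the list alone, and the list was not called (adjusted p = 0.627). Among those that fell was Idh1, the cytosolic isocitrate dehydrogenase (-1.40 ± 0.23). Inflammasome genes rose in 11 of 16 cases and fell in 5, also when adjusted over the list alone, with Mefv at 6.56 ± 0.44 and Nlrp1b at -3.03 ± 0.39 (adjusted p = 0.276 for the list with an estimated correlation). Dendritic cell markers rose in 8 of 13 cases, also when adjusted over the list alone, with the actin-bundling gene Fscn1 at 4.92 ± 0.27 (adjusted p = 0.137 for the list with an estimated correlation). From control to 8 h, mean marker sums went from 137 to 380 CPM for neutrophils, 121 to 348 CPM for stromal cells and 6.86 to 183 CPM for mast cells and basophils. They went from 17 to 11.9 CPM for B cells and 179 to 121 CPM for T and NK cells. Such sums can follow single genes: Hdc, of the mast cell list, reached 184 CPM.

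Neutrophil markers summed to 34.6 to 55.7 CPM in WT-labelled controls of set A and 214 to 243 CPM in those of set B. In KO-labelled controls the sums were 70.1 to 74.3 CPM in set A and 130 to 150 CPM in set B. The difference between KO-labelled and WT-labelled libraries was not the same in both sets for 252 genes in controls, 280 at 2 h and 736 at 8 h. These calls rest on the spread between libraries within a set. Nothing says that those libraries came from separate cultures or animals. The calls therefore do not separate an effect of genotype from a difference between single cultures.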
